A study of Oryza sativa Indica Group with 16 samples.

How the data were processed

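Transcript levels were measured on Affymetrix rice genome arrays in 10-day-old rice seedlings of 4 genotypes. CSR27 is the salt-tolerant parent and MI48 the salt-sensitive parent of a set of recombinant inbred lines, and the tolerant bulk and the sensitive bulk are pools of lines from that set. Each genotype was sampled under control conditions and after 24 h of 150 mM NaCl, with 2 arrays per group, 8 groups and 16 arrays, each from 8 µg of total RNA per the labels' protocols. The labels call the 2 arrays of a group biological replicates and do not say how the plants were divided, so a p-value measures the spread between these arrays.

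The deposited values are probe set signals, that is intensity on a linear scale, made with GCOS 1.2 per the submitters' processing notes. The algorithm's settings and its scaling are not given in the sources used here. The arrays had no common scale. The 2% trimmed mean was 500 on the array of MI48 salt replicate 1 and from 0.881 to 160 on the other arrays, and the log2 medians differed by up to 7.75. By the rule fixed for that case, each array was scaled so that its log2 median equalled the common median. The 123 control probe sets were left out, which left 57258 of 57381 probe sets. A probe set was tested if its scaled value was at or above the median of all values (14.9) on at least 2 of the 16 arrays, and 50528 were tested. Values were analysed as log2(value + pseudocount) with a pseudocount of 3.72, the 25th percentile of all values, so folds of dim probe sets are understated. The table holds no detection calls.

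Some arrays held little or no rice signal. The arrays of CSR27 control replicate 2 and CSR27 salt replicate 1 held no rice signal: their rank correlations with all other arrays lay between -0.0012 and 0.01, against a limit of 0.1, and their 99th percentiles were 4.3 and 4.1. Hybridisation spike-ins were bright on them (medians 1140 and 703), while the poly-A spike-ins had medians of 0.3 and 0.45. CSR27 therefore had 1 array with rice signal per condition. The other 6 parent arrays correlated with each other at Spearman rho of 0.64 to 0.77, and the 8 bulk arrays at 0.9 to 0.93.

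Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p, threshold 0.05). The design fixed before the data were examined was a group-means model over all 16 arrays, in which the arrays share 1 estimate of the spread, and its counts stand beside every comparison. After the data and the counts of calls of several fits had been seen, 2 further fits were added: one of the 14 arrays with rice signal, and one of the 8 bulk arrays alone, with scaling, filter and pseudocount (3.86) taken from those 8 and 32977 probe sets tested. The reason for the second is that the parent arrays widen the shared spread: the median residual SD was 0.923 with 16 arrays, 0.582 with 14 and 0.262 with the 8 bulk arrays. Genes of the bulks are described from this added fit, which was not planned and which calls more probe sets than the planned one. On simulated data for the salt response of the tolerant bulk, with 100 probe sets changed at each size, the 8-array fit recovered 19 at a log2 change of 1 and 56 at 2, with 4 false calls. The 16-array fit recovered 0 at a log2 change of 2 and 19 at 4. All simulated arrays had the same spread per probe set, pooled over the groups, and no shifts of whole arrays. The simulated bulk arrays of the 16-array fit thus carried the spread of the parent arrays, unlike the real ones. Neither the recovery nor the false calls carry over to the real arrays, and they do not justify the added fit.

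Alternatives fixed with the design were quantile normalization, no filter, 0.25 of the pseudocount, the replicate number as a block, only the arrays compared, and each array left out in turn, where the lone array of a group is assumed to vary like the others. The replicate numbers did not pair the arrays: the correlations of the differences between replicates 1 and 2 in different groups ran from -0.52 to 0.15 over 28 pairs of groups, and 2 were over 0.1. Quantile normalization is given beside median scaling for the splits of rises and falls that it moved by more than 10 percentage points, because median scaling left the median of all probe sets off 0 (by -0.14 on the log2 scale in the averaged response of the bulks).

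Probe sets were named through the platform's annotation, matched by gene ID to a gene table of assembly ASM3414082v1, from which names and gene order alone were used. One gene was given for 22436 probe sets, several for 95 and none for 34727. All 17905 gene IDs matched, and 2457 genes had a name other than a locus number, so most called probe sets go unnamed. Gene lists were tested with camera (preset correlation 0.01, and with an estimated correlation). Of 33 lists, 26 were fixed at the same time as the design. Their patterns had been written for gene descriptions, which the table lacks, so they were matched on symbols and synonyms instead, after the annotation had been read. The other 7, DNA replication and diterpenoid phytoalexin synthesis among them, were added after the annotation was read and before differences were looked at gene by gene. In the 8-array fit 68 of 192 list tests passed with the preset correlation, 2 with an estimated one (seed storage between the bulks in control and in the difference of their responses) and 61 after quantile normalization. In the 16-array fit 84 of 363 passed, 2 with an estimated correlation and 60 after quantile normalization.

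Genes were named by a fixed rule, among called probe sets with exactly 1 gene and a name, 1 probe set per gene by largest log2 fold. The averaged response takes 12 in each direction with the same sign in all genotypes, the salt comparisons between genotypes take 10 and other comparisons 5, with both arrays of a group beyond both of the other. Up to 4 called members per list, and every measured gene of a list of salt tolerance genes studied in rice, were added. The rule was applied to the 16-array calls and, for the bulks, to the added 8-array fit. The text gives a part of those names. Figures were drawn with matplotlib 3.10.9.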

Results

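The study compared rice seedlings of a salt-tolerant parent (CSR27), a salt-sensitive parent (MI48) and bulks of tolerant and sensitive recombinant inbred lines, each with and without 24 h of 150 mM NaCl. There were 16 arrays in 8 groups of 2, a number that limits the precision of every value. Deposited signals differed in brightness. Array medians ran from 0.4 to 86.3 over all arrays and from 14.8 to 26.1 over the 8 bulk arrays. Probe sets of reference genes such as tubulins and actins had median signals of 608 to 1800 on the bulk arrays and 0.7 on both CSR27 arrays without rice signal.

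**Figure D1:**
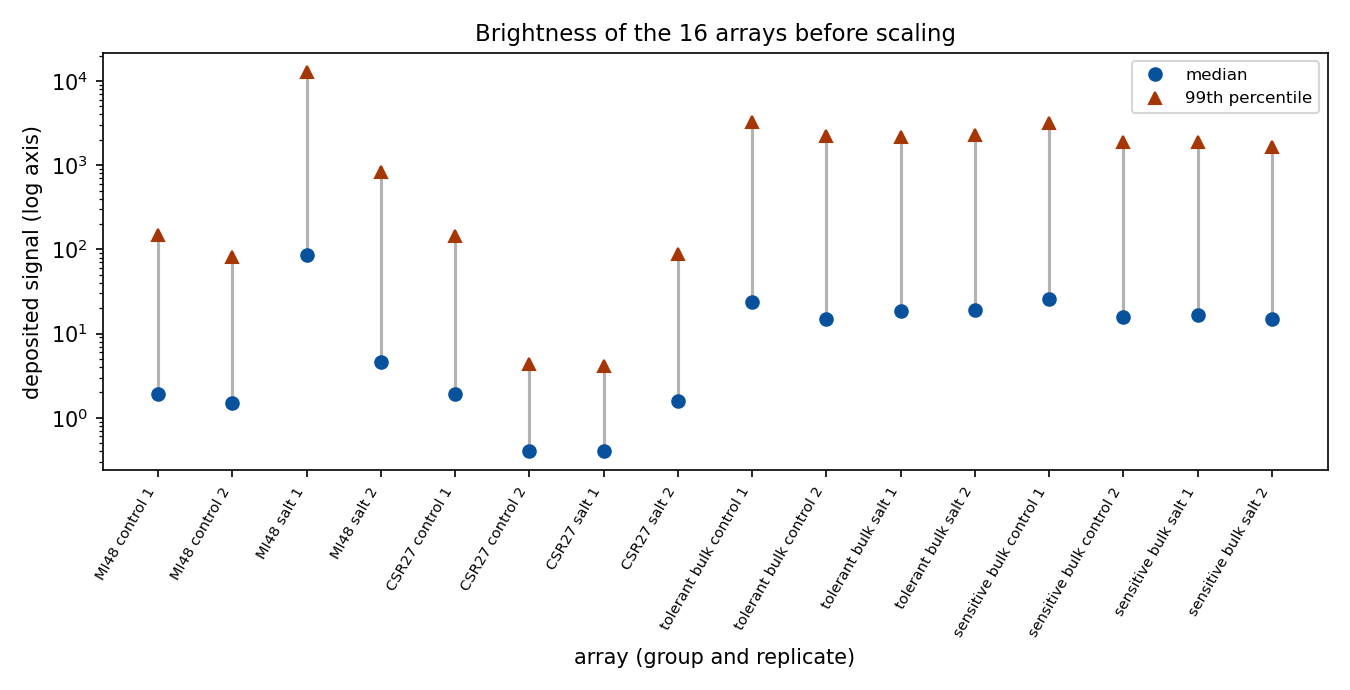
Deposited signal of each of the 16 arrays before scaling, on a log axis, with circles for the median of all rice probe sets and triangles for the 99th percentile. The 8 bulk arrays have medians from 14.8 to 26.1, MI48 salt replicate 1 reaches 86.3, and the 99th percentiles of CSR27 control replicate 2 and CSR27 salt replicate 1 are 4.3 and 4.1.

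The planned fit of all 16 arrays called 0 probe sets for the salt response of either bulk and for any difference between the bulks (limma). At an unadjusted p under 0.05 it held 256 for the tolerant bulk, 247 for the sensitive bulk, 158 between the bulks in control, 145 in salt and 115 for the difference of the responses. Without any difference a share of 0.05 of the 50528 tested would be expected there, far more than each of these counts. The shared spread is thus too wide for the bulks, and the counts do not measure remaining differences. The same holds for the bulk counts at an unadjusted p in the 14-array fit, of 42273 tested. Every such count below is to be read against that share. Genes of the bulks are given below from a fit of the 8 bulk arrays alone, which was added after the data and the counts of calls of several fits had been seen, and all calls in the bulks carry that limit.

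Dehydrin transcripts rose in the average response to salt over both bulks. RAB16B (log2 4.53 ± 0.14, SE, 4 salt and 4 control arrays, limma adjusted p = 4.6e-08) and RAB21 (4.26 ± 0.1), both dehydrins, had the largest rises among the genes named by the rule. LEA3-1, a late embryogenesis abundant protein, rose by 3.56, HOX24, a homeodomain transcription factor, by 3.59, and the dehydrins RAB16D and RAB16C by 2.99 and 2.28. The protein phosphatases OsPP2C59 and PP2C30 rose by 2.92 and 2.14, and the chitinase Cht1 by 2.11. BURP16 fell by 2.24, OsPIN5a, of the PIN family of auxin carriers, by 2.01, GRXC15, a glutaredoxin, by 1.94, and HAK17, a potassium transporter, by 1.92. SWEET11, a sugar transporter, fell by 1.46 ± 0.11 and CKX4, a cytokinin oxidase, by 1.46 ± 0.11. These genes had the same sign in both bulks, which the rule for naming them required.

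**Figure D2:**
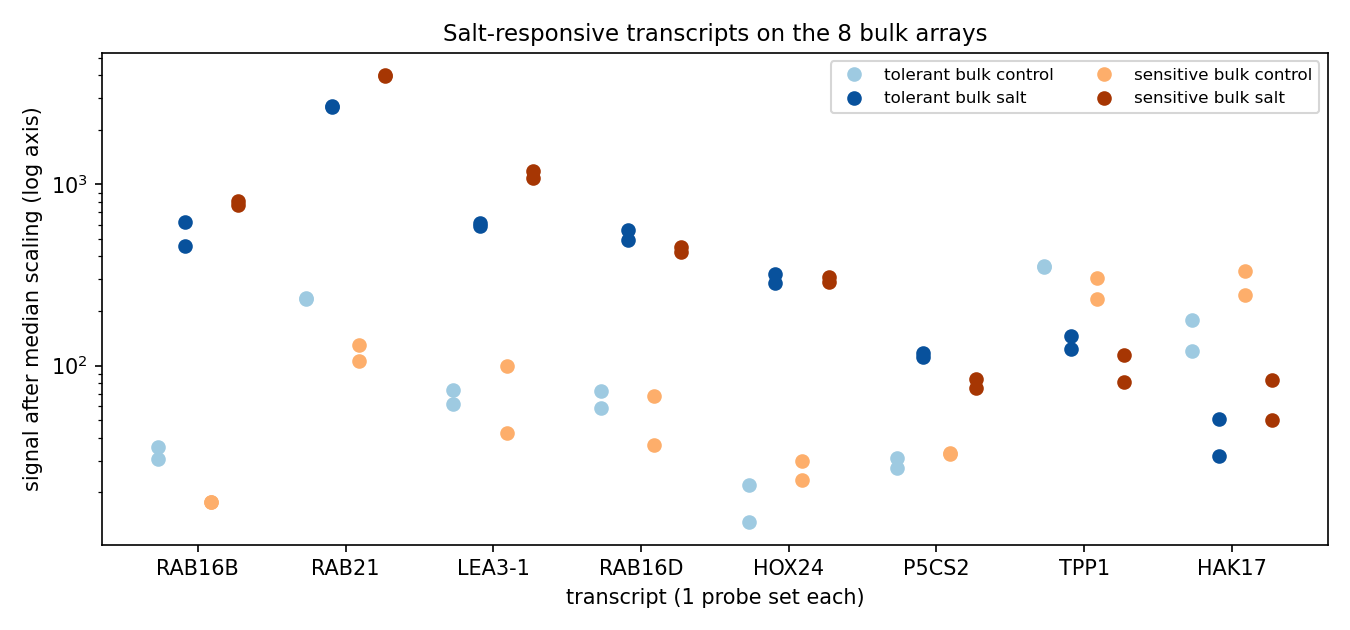
Median-scaled signal of 8 transcripts on the 8 bulk arrays, on a log axis, where each point is 1 array and the colours give the 4 groups. RAB16B lies at 35.4 and 30.4 in the tolerant control, 621 and 457 in the tolerant salt arrays, 17.8 on both sensitive control arrays, and 813 and 765 in the sensitive salt arrays.

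Of 32 gene lists tested with camera on this averaged response, 10 passed with the preset correlation and 0 with an estimated one. Of 8 dehydrin and late embryogenesis abundant probe sets 7 rose and 0 fell, also when adjusted over the list alone, with a list median of 3.23 (camera adjusted p = 2.7e-22, and adjusted p = 0.13 with an estimated correlation). Of 19 probe sets of salt tolerance genes studied in rice, a list that shares the dehydrins, 9 rose and 1 fell, also adjusted over the list alone (adjusted p = 4.1e-13, and adjusted p = 0.17 with an estimated correlation). Of 61 heat shock probe sets 16 rose and 6 fell, and 17 and 9 adjusted over the list alone (adjusted p = 1.6e-06, and adjusted p = 0.54 with an estimated correlation). The small heat shock proteins HSP18.6 and HSP16.9B rose by 2.09 and 1.69, and HSP18.8 fell by 1.44. Of 24 histone and cyclin probe sets 11 fell and 0 rose, and 12 fell adjusted over the list alone (adjusted p = 3.4e-04, and adjusted p = 0.43 with an estimated correlation). CYCB1-1, a cyclin, fell by 0.91. Of 16 probe sets for nitrogen uptake and assimilation 6 fell and 0 rose, and 9 fell adjusted over the list alone (adjusted p = 6.5e-04, and adjusted p = 0.43 with an estimated correlation). They included GLN1-2, a glutamine synthetase, which fell by 1.27. Among 31 DNA replication probe sets 10 fell and 0 rose (adjusted p = 3.0e-04, and adjusted p = 0.54 with an estimated correlation). Of 33 reference gene probe sets 9 fell and 0 rose, and after quantile normalization 8 fell and 4 rose (adjusted p = 0.054, and adjusted p = 0.82 with an estimated correlation).

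The averaged response held 867 probe sets that rose and 4040 that fell of 32977 tested, against 1828 and 2116 after quantile normalization, which removes a median shift of -0.14. Some bright probe sets moved by more. In the tolerant bulk RPL11 went from -0.57 to -0.26 and SODCC.2 from 0.81 to 1.07, while the dim DREB1B went from 2.42 to 2.39. Except for the reference genes, the lists above are counted under median scaling alone. Without sensitive bulk control replicate 2 the 8-array count was 9287. It was 2336 and 2535 without tolerant bulk control replicates 1 and 2, 2804 and 2762 without tolerant bulk salt replicates 1 and 2, and 2953 and 2410 without sensitive bulk salt replicates 1 and 2. The planned average over 4 genotypes, from all 16 arrays, called 18 probe sets, all higher, with OsPP2C59 (3.5 ± 0.55, adjusted p = 0.039) and HOX24 (3.25 ± 0.55, adjusted p = 0.046) among them. Of 100 splits of the arrays within genotypes 30 called as many. These splits can set both CSR27 arrays without rice signal on the same side, which the real one does not, so they do not measure chance alone. Chance is not excluded for these 18. Quantile normalization gave 0 calls there (limma, with 2577 at an unadjusted p under 0.05), and so did leaving out any 1 of the 8 bulk arrays, MI48 control replicate 1 or MI48 salt replicate 2. Without MI48 control replicate 2 or MI48 salt replicate 1 the count was 61 or 1. It was 334 and 70 without CSR27 control replicates 1 and 2, and 120 and 51 without CSR27 salt replicates 1 and 2.

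In the tolerant bulk RAB16B rose by 3.87 ± 0.2 (log2, SE, n = 2 and 2, limma adjusted p = 3.5e-06), HOX24 by 3.85, RAB21 by 3.49, LEA3-1 by 3.08 and RAB16D by 2.94. P5CS2, an enzyme of proline synthesis, rose by 1.84 ± 0.23 and DREB1B, an AP2/ERF transcription factor, by 2.42 ± 0.54. Seed transcripts made up the 5 largest named falls. RA14 fell by 3.56 ± 0.24, the prolamin PROLM25 by 3.41, the glutelins GLUD-1 and GLUB-5 by 3.25 and 3.2, and GBSS1, a granule-bound starch synthase, by 2.87. Other probe sets of RA14 changed less, by -0.3, -0.04 and -1.71. Of 22 seed storage and endosperm probe sets 6 fell and 0 rose, and 10 fell adjusted over the list alone (camera adjusted p = 1.0e-04, and adjusted p = 0.15 with an estimated correlation). The potassium transporters HAK17 and HAK5 fell by 1.76 and 1.74. Of 26 leaf photosynthesis probe sets 8 fell and 0 rose, and 11 fell adjusted over the list alone (camera adjusted p = 2.1e-06, and adjusted p = 0.56 with an estimated correlation). After quantile normalization 4 of them fell. OsrbcS, the small subunit of Rubisco, fell by 1.13 ± 0.19. In total 325 probe sets rose and 1460 fell, against 745 and 897 after quantile normalization. The 14-array fit called 3 and the planned fit of the 4 arrays compared called 2595. Without tolerant bulk control replicates 1 and 2 the 8-array count was 498 and 379, and without tolerant bulk salt replicates 1 and 2 it was 541 and 538.

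In the sensitive bulk RAB16B rose by 5.19 ± 0.2 (log2, SE, n = 2 and 2, limma adjusted p = 4.3e-07), RAB21 by 5.03, LEA3-1 by 4.04, PM1 by 3.33 ± 0.27 and HOX24 by 3.33 ± 0.24. P5CS2 rose by 1.2 ± 0.23. The salt-induced lectin salT rose by 1.07 ± 0.14, with 0.43 ± 0.14 in the tolerant bulk (adjusted p = 0.11), where it passed after quantile normalization (0.68, adjusted p = 0.0067). The difference of the responses of salT passed under neither scaling (adjusted p = 0.54 and 0.34). Among chitinases Cht1 rose by 2.69 and Cht-3 by 1.87. Of 22 pathogenesis-related and protease inhibitor probe sets 6 rose and 1 fell, and 8 and 3 adjusted over the list alone (camera adjusted p = 5.6e-05, and adjusted p = 0.32 with an estimated correlation). Of 22 seed storage and endosperm probe sets 5 rose and 0 fell, and 8 and 1 adjusted over the list alone (adjusted p = 4.2e-06, and adjusted p = 0.081 with an estimated correlation). PROLM25 rose by 2.98, the alpha-amylases AMY1.4 and AMY1.1 by 1.91 and 1.8, and RA14 by 1.7. Other probe sets of RA14 had 1.12, 0.41 and 0.12. OsPIN5a fell by 2.54 ± 0.44, GRXC15 by 2.26, HAK17 by 2.08 ± 0.31, PHO1-3, of the PHO1 family of phosphate exporters, by 2.08 ± 0.51, and NH4 by 1.93. MCM4, a replication licensing factor, fell by 1.2 and PCNA, the sliding clamp of replication, by 0.89. In total 576 probe sets rose and 1576 fell, against 1089 and 1040 after quantile normalization. The 14-array fit called 2 and the planned fit of the 4 arrays compared called 132. Without sensitive bulk control replicate 2 the 8-array count was 7235, and without sensitive bulk salt replicates 1 and 2 it was 546 and 360.

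The bulks shared part of these responses. Of the probe sets that rose, 211 did so in both bulks, where independent lists would share 5.68, and 690 fell in both, where 69.8 would be shared. The 2 responses have no array in common, but they come from the same fit with a shared spread per probe set. Both also carry a downward median shift (-0.14 and -0.15). The lists are therefore not independent, and the expected numbers are only a guide. TPP1, a trehalose phosphate phosphatase, fell by 1.37 in the tolerant and by 1.43 in the sensitive bulk. HKT1;5, a sodium transporter, did not pass the test in either bulk (0.25 ± 0.23 and 0.08 ± 0.23), nor did CIPK24, a protein kinase (0.19 ± 0.15 and -0.03 ± 0.15). P5CS1, of proline synthesis, had 0.47 ± 0.19 and 0.43 ± 0.19 under median scaling (adjusted p = 0.2 and 0.21) and passed in both bulks after quantile normalization (0.71 and 0.67, adjusted p = 0.014 and 0.017). In the average of the bulks P5CS1 rose by 0.45 (adjusted p = 0.044).

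Under control conditions several seed transcripts were higher in the tolerant bulk. PROLM25 was higher by 5.83 ± 0.23 (log2, SE, n = 2 and 2, limma adjusted p = 9.7e-07), RA14 by 4.55, GBSS1 by 3.77, GLUB-5 by 3.5 and AMY1.1 by 2.59. Other probe sets of RA14 had smaller differences (1, 0.27 and 2.09). Of 22 seed storage and endosperm probe sets 7 were higher and 0 lower, and 11 were higher adjusted over the list alone (camera adjusted p = 3.6e-11, and adjusted p = 0.046 with an estimated correlation). The heat shock factors HSFA2D (-1.73 ± 0.16), HSF25 (-1.53) and HSF1 (-1.3) and the small heat shock protein HSP18.1 (-1.28) were lower in the tolerant bulk, while HSP23.2 (2.11) and HSP16.9B (1.99) were higher. AARE2 was higher (3.21 ± 0.5) and PCL1 lower (-3.06 ± 0.52). In total 391 probe sets were higher and 89 lower, against 369 and 352 after quantile normalization. The 14-array fit called 1 and the planned fit of the 4 arrays compared called 33. Without tolerant bulk control replicates 1 and 2 the 8-array count was 197 and 110, and without sensitive bulk control replicates 1 and 2 it was 3132 and 1409.

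**Figure D3:**
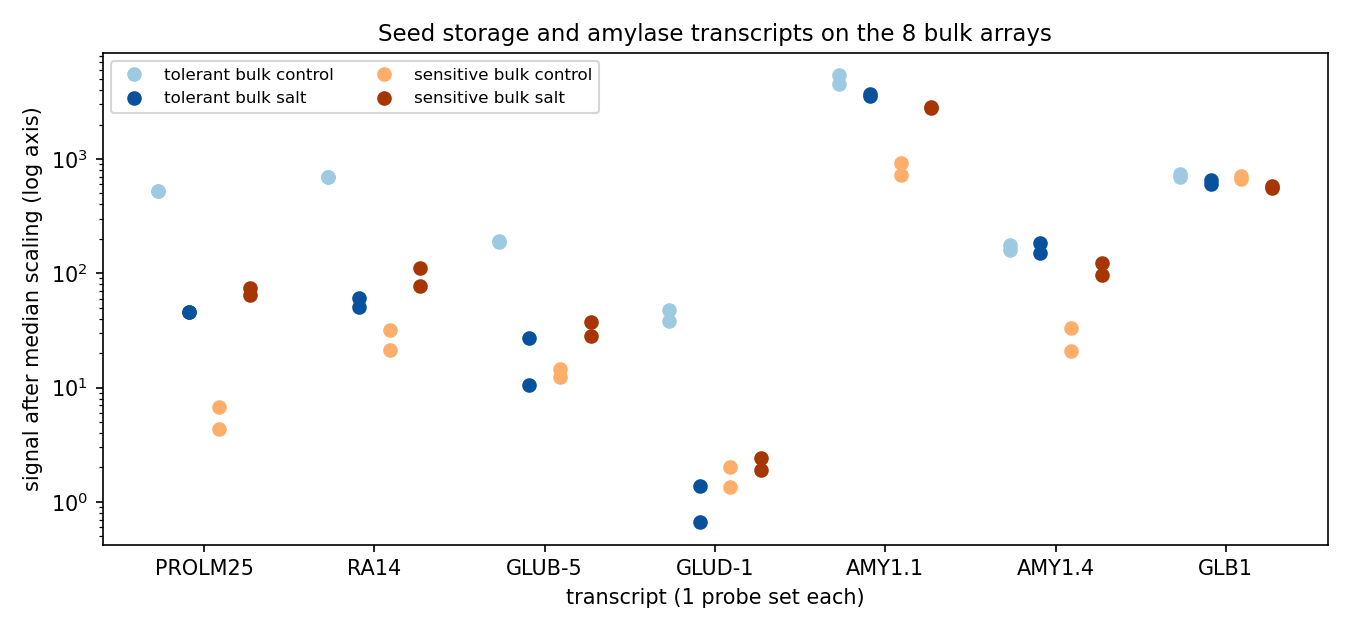
Median-scaled signal of 7 seed storage and amylase transcripts on the 8 bulk arrays, on a log axis, where each point is 1 array and the colours give the 4 groups. PROLM25 lies at 526 and 527 in the tolerant control, 46 and 45.9 in the tolerant salt arrays, 6.72 and 4.35 in the sensitive control, and 65.1 and 75 in the sensitive salt arrays.

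After salt G1L9 was higher in the tolerant bulk by 1.63 ± 0.28 (log2, SE, n = 2 and 2, limma adjusted p = 0.022), NMCP1A by 1.46, MAN1 by 1.33, the translation initiation factor eIF-4G by 1.25, JAZ10, a jasmonate repressor, by 1.23 and the metallothionein MT1B by 1.16. HSFA2D (-1.54 ± 0.16), Fd-GOGAT, a glutamate synthase (-1.47), ELA3 (-1.45), TRXM, a thioredoxin (-1.18), OsrcaA1, a Rubisco activase (-1.08), KSL7, a diterpene synthase (-1.07), and salT (-0.85) were lower. Of 26 leaf photosynthesis probe sets 2 were lower and 0 higher, and 7 were lower adjusted over the list alone (camera adjusted p = 2.5e-10, and adjusted p = 0.46 with an estimated correlation). In total 237 probe sets were higher and 186 lower, against 349 and 573 after quantile normalization. The 14-array fit called 0 (limma, with 882 at an unadjusted p under 0.05) and the planned fit of the 4 arrays compared called 621. Without either tolerant bulk salt array the 8-array count was 0, and without sensitive bulk salt replicates 1 and 2 it was 14 and 4, so these calls rest on each of the 4 arrays.

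The salt response itself differed between the bulks for 57 probe sets, 5 with a larger and 52 with a smaller value in the tolerant bulk. PROLM25 (-6.4 ± 0.32, log2 difference of responses, SE, limma adjusted p = 9.4e-06), RA14 (-5.25), GBSS1 (-4.92), GLUB-5 (-4.29) and AMY1.1 (-2.24) differed most among called genes with a name. Other probe sets of RA14 had -1.41, -0.46 and -1.82 and were not called. Of 22 seed storage and endosperm probe sets 5 were called, and 9 adjusted over the list alone (camera adjusted p = 8.4e-16, and adjusted p = 0.024 with an estimated correlation). RAB21 differed by -1.54 ± 0.19 (limma adjusted p = 0.0074), PBZ1, a pathogenesis-related protein, by -1.8, and HSP18.1 by 1.27. The log2 means of RAB21 were 7.9 in the tolerant and 6.92 in the sensitive control, and 11.39 and 11.96 after salt. Its levels in control thus contributed to the difference of the responses. The median of the 8 dehydrin and late embryogenesis abundant probe sets was -0.93 (adjusted p = 4.8e-09, and adjusted p = 0.22 with an estimated correlation). The 14-array fit called 0 (limma, with 496 at an unadjusted p under 0.05) and the planned fit of the 8 arrays compared, with the filter of all 16, called 37. Without tolerant bulk control replicates 1 and 2 the 8-array count was 29 and 25, without tolerant bulk salt replicates 1 and 2 it was 28 and 26, without sensitive bulk control replicates 1 and 2 it was 210 and 281, and without sensitive bulk salt replicates 1 and 2 it was 27 and 25.

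In MI48 the planned 16-array fit had the small heat shock protein HSP18.6 risen by 5.98 ± 1.17 with salt (log2, SE, n = 2 and 2, limma adjusted p = 0.034), OsPP2C59 by 5.8, HSP18.1 by 5.7, HOX24 by 5.61 and BGLU16 by 5.26, and osysl15 fell by 4.64. Of 66 heat shock probe sets 6 rose and 0 fell, and 27 rose adjusted over the list alone (camera adjusted p = 2.6e-11, and adjusted p = 0.061 with an estimated correlation). The 16-array spread is shared with the bulk arrays, which varied less, and the planned fit of only the arrays compared called 0 (limma). In total 191 probe sets rose and 11 fell in the 16-array fit. Quantile normalization gave 0 calls (limma, with 2808 at an unadjusted p under 0.05), while with 14 arrays 9844 rose and 1427 fell, and 2581 and 2309 after quantile normalization of the 14. The MI48 control arrays were dim (medians 1.9 and 1.5) and the salt arrays brighter (86.3 and 4.6). Without MI48 control replicates 1 and 2 the count was 16 and 112, and without MI48 salt replicate 2 it was 15.

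In CSR27, with 1 array per condition that held rice signal, no probe set passed the threshold (limma, 0 calls, with 6478 at an unadjusted p under 0.05). This fit also held the other CSR27 array of each condition, which had no rice signal. The 0 calls therefore do not show that CSR27 lacked a response. Counts from fits without those arrays are given below with the dependence on the processing. Without CSR27 control replicate 1 or CSR27 salt replicate 2 the count was 6559 or 6269, but in these fits the left-out array was the group's only one with rice signal. No probe set passed between the parents under control conditions (limma, 0 calls, with 5825 at an unadjusted p under 0.05). That comparison too held a CSR27 array without rice signal, control replicate 2, so it does not show that the parents were alike.

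After salt MADS21, a MADS-box transcription factor, was higher in CSR27 than in MI48 (3.4 ± 0.72, log2, SE, limma adjusted p = 0.02), and the small heat shock protein hsp17.9 (-7.01) and HOX24 (-6.25) were lower, in a fit of 2 arrays each of which 1 CSR27 array, salt replicate 1, held no rice signal. Without that array the values were 3.05 ± 0.69 for MADS21, -4.45 ± 1.43 for hsp17.9 and -4.32 ± 1.1 for HOX24, and none of the 19 differences named by the rule passed (limma adjusted p = 0.073, 0.17 and 0.099 for these genes). Of 88 probe sets for abscisic acid synthesis and signalling 24 were lower and 0 higher, and 49 were lower adjusted over the list alone (camera adjusted p = 5.1e-09, and adjusted p = 0.38 with an estimated correlation). Without CSR27 salt replicate 1 the list had 1 lower and 0 higher. In total 595 probe sets were higher and 3407 lower, and without CSR27 salt replicate 1 these were 7 and 204. Quantile normalization left 0 calls (limma, with 8080 at an unadjusted p under 0.05). The planned fit of only the arrays compared, which also held CSR27 salt replicate 1, called 0 (limma). Without MI48 salt replicates 1 and 2 the count was 343 and 78, and without CSR27 salt replicate 2 it was 18350. The difference of the responses of the parents called 1 probe set, of a gene without a name in the gene table (-7.94 ± 1.11, adjusted p = 0.049). This fit held both CSR27 arrays without rice signal, so the count does not measure how far the responses of the parents differed. Counts from fits without these arrays are given below with the dependence on the processing.

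The parents and the bulks shared 0 called probe sets in the planned fit, in control or in salt, since no difference between the bulks was called there (limma, with 158 and 145 at an unadjusted p under 0.05). Of the 4002 probe sets called between the salt-treated parents, 38.2% had the same sign between the salt-treated bulks, against 44.2% of all tested, with a slope of -0.02. These calls come from a fit in which CSR27 salt replicate 1 held no rice signal, and quantile normalization left 0 of them. Median scaling left the medians of all probe sets on opposite sides of 0, at -0.26 between the parents and 0.06 between the bulks. With parents from 14 arrays and bulks from 8, after quantile normalization, the shares were 52.2% and 51.6%. The values are not evidence of a reversal. Probe sets are not independent replicates. The planned test for neighbouring shared genes had no genes to run on.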

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

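The test of array scaling was chosen after the result was seen, as was the fit of the 8 bulk arrays that all bulk values of this part come from. A test of the difference itself marked the salt responses of the bulks as different for 57 probe sets. By gene, at a called probe set, the log2 differences of the responses, tolerant minus sensitive bulk, were PROLM25 -6.4, RA14 -5.25, GBSS1 -4.92, GLUB-5 -4.29, AMY1.1 -2.24, PBZ1 -1.8, RAB21 -1.54, peroxidase -1.26 and HSP18.1 1.27. Other probe sets of RA14, at -1.41, -0.46 and -1.82, were not called. Between the parents the same kind of test marked 1 probe set in the 16-array fit, which held both CSR27 arrays without rice signal.

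Of 22 seed storage probe sets 7 were higher in the tolerant bulk in control, 6 fell with salt in the tolerant bulk and 5 rose in the sensitive bulk, while others such as GLB1 (-0.19 and -0.28 in the 2 responses) were not called. Scaling of the arrays is argued against for the called members by the size of their differences of responses, -2.24 to -6.4. The median of all probe sets in that comparison was 0.01 under either scaling. That 5 list members were still called after quantile normalization adds little, since differences of that size could hardly have been removed by it. RNA from remaining seed tissue in some of the samples stays open. If it were the cause, rho across the 22 list members between the 2 responses was predicted at or below -0.5, and otherwise at or above -0.2. The value was -0.11, past the bound of -0.2 but by less than its spread of 0.23, a margin brought in after the value was seen. Several of the 22 members lie near the floor, where ranks carry little, and the list holds alpha-amylases beside storage transcripts. The rho therefore decides nothing. A difference between the bulks in their use of seed reserves was not tested.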

How the results depend on the processing

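The fits of 14 and 8 arrays were chosen after the result was seen, and the other alternatives were planned for the 16-array fit. No named gene that was called changed sign under the alternatives run. The split of calls did turn after quantile normalization, from 237 higher and 186 lower to 349 and 573 between the bulks in salt, and from 576 rises and 1576 falls to 1089 and 1040 in the sensitive bulk, both in the 8-array fit. The cause was not tested except where a setting leaves out arrays or probe sets. Parent counts compare dim arrays and arrays without rice signal with brighter ones. Of 370 results on named genes called in the 8-array fit, 327 stayed called after quantile normalization, 286 without a filter, 360 with a smaller pseudocount and 367 with the replicate block. In 1988 comparisons of called results with 1 array left out, 1329 stayed called. Of 82 results on named genes not called there, 7 passed after quantile normalization, and of their 432 comparisons with 1 array left out 8 passed. In the 16-array fit 0 of 27 stayed called after quantile normalization, 20 without a filter, 16 with a smaller pseudocount and 20 with the replicate block, and 34 of 132 comparisons with 1 array left out.

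Quantile normalization moved the count in MI48 from 202 to 0, the 4-genotype average from 18 to 0, the parents in salt from 4002 to 0, and the interaction of the parents from 1 to 0. In the 8-array fit it moved the bulks from 480 to 721 in control and from 423 to 922 in salt. With 0.25 of the pseudocount these were 108 (MI48), 2 (average), 2487 (parents in salt) and 0 (interaction of the parents). Without a filter they were 2 (average) and 0 (interaction of the parents), and in the 8-array fit 1364 (sensitive bulk), 298 and 208 (bulks in control and salt) and 36 (interaction of the bulks). With the replicate number as a block the parents in salt gave 2569 and their interaction 0, although the numbers do not pair the arrays.

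With 14 arrays the counts were 11271 (MI48), 189 (CSR27), 3 and 2 (tolerant and sensitive bulk), 1425 (average), 46 and 9679 (parents in control and salt), 1 (bulks in control) and 4597 (interaction of the parents). With quantile normalization of the 14 they were 4890, 1212, 2 (sensitive bulk), 1915 (average), 525 (parents in control), 2 (bulks in control) and 1517, and the parents in salt gave 3156 (1243 higher and 1913 lower, against 883 and 8796 with median scaling). With the 14 arrays the split in CSR27 went from 58 rises and 131 falls to 540 and 672 after quantile normalization, in the average from 1039 and 386 to 1030 and 885, and in the interaction of the parents from 578 and 4019 to 637 and 880. With the 8 bulk arrays they were 1785 and 2152 (salt in the tolerant and sensitive bulk), 480 and 423 (bulks in control and salt) and 57 (interaction). With only the arrays compared they were 0 for MI48, the parents in salt and their interaction, and 2595, 132, 33, 621 and 37 for the same 5 bulk comparisons. Scaled and filtered as the 8 arrays, these were 4195, 381, 134 and 1741 for the first 4. Parents and bulks shared 32 in salt with parents from 14 and bulks from 8 arrays, and 6 in control and 48 in salt after quantile normalization. The share with the same sign as in the parents was then 34.2%, against 43.1% of all tested, and after quantile normalization 52.2%, against 51.6% of all tested. List tests past the threshold fell to 2 with an estimated correlation in either fit.

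Leaving out 1 array gave 15 to 202 calls in MI48, 0 to 6559 in CSR27, 0 to 334 in the average, 0 to 14479 and 78 to 18350 between the parents in control and salt, and 0 to 5652 in their interaction. In the 8-array fit it gave 379 to 541 in the tolerant bulk, 360 to 7235 in the sensitive bulk, 2336 to 9287 in their average, 110 to 3132 and 0 to 14 between the bulks in control and salt, and 25 to 281 in their interaction. The share carried over has no value in the 16-array fit with quantile normalization, nor has the neighbour test of shared genes, as no genes were called. The highest counts for CSR27, the average, the parents and their interaction come from fits without a group's only CSR27 array with rice signal.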

Other observations

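The fits of 14 and of 8 arrays behind the bulk values here, the shared sets taken from them, the splits within each genotype, the arrays left out below and the reading of the neighbour test were chosen after the results were seen, while the other tests were fixed before their values were known. In the sensitive bulk EREBP-1, an AP2/ERF factor, rose by 2.06 ± 0.42 and CYP99A2, of diterpenoid phytoalexin synthesis, by 1.98 ± 0.41 (limma, n = 2 and 2 arrays, both adjusted p = 0.018). After salt 13 probe sets of that pathway had a median of -0.63 in the tolerant minus the sensitive bulk (camera adjusted p = 1.0e-05, and adjusted p = 0.2 with an estimated correlation), with KSL7 called. Cell wall expansion probe sets had a median of 0.47 in the same comparison, with 1 of 25 called, EXPB4 (0.69), and 5 adjusted over the list alone (adjusted p = 5.1e-04, and adjusted p = 0.54 with an estimated correlation).

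A model of 2 groups, 4 salt and 4 control bulk arrays, called 2554 probe sets. Of the 35 splits of these arrays into 4 and 4 only 1, the real one, called as many. That is the smallest share 35 splits can give. Every other split mixed salt and control arrays within a group, which adds the salt response to the spread and lowers the count. The test therefore does not exclude chance by itself, and its model is not the one behind the averaged response above. The highest of the other splits, with 141, parted the tolerant from the sensitive bulk. For all 16 arrays a model of 2 groups called 0 for the real split (limma), which all 100 of its splits had to match, so it decides nothing, and the highest of them called 338. In the model that gave the 18 calls of the average over 4 genotypes, 30 of 100 splits that dealt the 4 arrays of each genotype into 2 and 2 called as many. The highest of the others called 7423. The real split has 1 CSR27 array without rice signal on each side, while other splits can set both on the same side. The splits therefore do not measure chance alone, and what raised their counts was not tested. Chance is not excluded for these 18 calls.

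Rises outnumbered falls in MI48. A difference in array brightness is a candidate explanation. Of the MI48 risers of the 14-array fit 35.3% rose in the average of the bulks, 0.157 percentage points above the 35.1% of all probe sets, where under 10 was predicted for this cause. A response of MI48 that the bulks lack would give the same value and stays open.

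Between the bulks 133 probe sets differed in the same direction in control and in salt and 6 in opposite directions, with no array shared, but the first count was 0 without either tolerant bulk salt array, 10 and 3 without sensitive bulk salt replicates 1 and 2, 49 and 38 without tolerant bulk control replicates 1 and 2, and 872 and 420 without sensitive bulk control replicates 1 and 2. Both differences come from the same fit with a shared spread per probe set, and both carry an upward median shift (0.09 in control and 0.1 in salt). The calls in control and in salt are therefore not independent. NMCP1A (1.85 and 1.46), eIF-4G (1.29 and 1.25) and MT4C (1.34 and 0.94) were higher in the tolerant bulk, and HSFA2D (-1.73 and -1.54) and pinA (-1.22 and -0.9) lower. Whether sequence differences under single probe sets contribute was not decided. Of 27 other probe sets of the same genes 74.1% had the same direction, which lies between the bounds set for and against. None of the 27 was called in both conditions, which weighs little because such calls depended on single arrays. That such genes lie in linked stretches of the genome was a hypothesis that did not pass its test, with 15 of 49 genes having another within 1 Mb where 13.1 were expected (one-sided permutation p = 0.36), 13 within 0.5 Mb where 7.3 were expected (p = 0.065) and 23 within 2 Mb where 21.7 were expected (p = 0.43). It stays open, because the bound written against it was a missed p, which excludes nothing, a reading adopted after the value was seen.

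With the parents taken from the 14 arrays and the bulks from the 8, after quantile normalization, 34 probe sets were higher in the tolerant genotype of both pairs after salt, where 9.85 would be shared by independent lists (exact hypergeometric p = 4.6e-10, across probe sets that are not independent). Of those lower 14 were shared where 31.4 would be. With median scaling the counts were 6 where 2.95 would be shared (exact p = 0.077) and 26 where 48 would be. CSR27 salt is 1 array in that fit, assumed to vary like the other groups. In control after quantile normalization the shared numbers lay near those of independent lists. The p-values here are for the higher direction alone, and the lower direction shared fewer than independent lists would. After quantile normalization 52.2% of the probe sets called between the salt-treated parents had the same sign between the bulks, against 51.6% of all tested, with a slope of -0.0022. The 34 are therefore no evidence that the parental differences as a whole recur in the bulks.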
